A study of Homo sapiens with 36 samples.

How the data were processed

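The 36 samples were primary mammary tumours of MDA-MB-231 D3H1 Luc cells, a luciferase-carrying derivative of a human triple-negative breast cancer line. They had been grown in Balb/c nude mice, which accept human cells because they lack mature T cells. Per the labels' protocols, mice received daily intraperitoneal sulforaphane (SFN) at 50 mg/kg, or 0.9% saline, for 2 weeks before and 3 weeks after injection of 50000 cells into mammary gland number 4. SFN is an isothiocyanate found in broccoli. The labels place 24 tumours in a growth stage, with tissue removed at day 35, and 12 in an initiation stage, with tissue removed before day 20. The protocol text gives resection at day 30, and the sources used here do not resolve this difference. The treatment text is the same for both stages. If days count from injection, removal before day 20 comes before 3 weeks of treatment are complete. How long initiation mice were treated after injection is thus uncertain. Samples were grouped by stage and treatment from the labels, which call the numbered samples of a group biological replicates. Nothing in the sources used here ties each sample to a separate mouse, and the test treated all 36 as independent.

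Per the series design text, the authors measured a custom NanoString nCounter codeset of 107 genes and controls, chosen as embryonic stem cell genes and markers of the epithelial-mesenchymal transition (EMT) and its reverse (MET). The nCounter counts colour-coded probes hybridised to single RNA molecules without amplification. Per the labels, 500 ng of total RNA entered each assay. The authors used nSolver 2.070 and selected genes at a p below 0.05 and a fold change of 1.5. The deposited values are nCounter signal per probe on a linear scale, in arbitrary units. Within each sample the signal lay on evenly spaced steps with an offset and a floor of 1, the form that a count has after subtraction of a background and scaling. The background, the scaling factors and the control probes are not given in the sources used here, so the depth behind a value and its counting error are unknown. No set of probes tested had a constant mean across samples, so the scaling could not be traced to reference probes. The precision of each group mean is limited by the number of tumours.

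All 107 genes were used, with no filter. Of their names, 104 matched a symbol in a table of gene names and 3 did not (CGB, NR6A1-2 and T). The RefSeq annotation used for gene copies lists TDGF1, TDGF1P3 and T as CRIPTO, CRIPTO3 and TBXT. Signal was converted to log2(signal + 1). Group means printed with an SD are means of signal. Counts of tumours below or above a group mean refer instead to the mean of log2(signal + 1). Differences were tested with limma 3.58.1 in R 4.3.3, in a single fit of 4 group means (lmFit, contrasts.fit and eBayes with default settings). The test was two-sided, with Benjamini-Hochberg adjustment over 107 genes within each comparison, and a gene passed at an adjusted p below 0.05. There were 5 comparisons. They were SFN against saline in growth tumours, SFN against saline in initiation tumours, the difference between those effects, their mean, and initiation against growth in saline tumours. On 20 simulated tables of the same size, the test recovered between 48% (difference between the effects) and 98% (mean of the effects) of genes that differed by 2 on the log2 scale. It recovered 94.5% in the growth, 68.5% in the initiation and 85% in the saline comparison. At a log2 difference of 1 it recovered 40% in the growth, 22.5% in the initiation and 32.5% in the saline comparison, 11% for the difference between the effects and 64.5% for their mean. Between 2.69% and 6.67% of its calls were false. The simulated noise was normal and independent between genes. In the tumours genes were correlated (0.44 estimated among the pluripotency factors), so these rates may not carry over to them.

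The named genes were set by a rule. Per comparison they were the genes that passed, at most the 15 largest differences each way, and where fewer than 10 passed, the genes of smallest p up to 10. Fixed genes were added whatever their values: TDGF1, TDGF1P3, NODAL, POU5F1, SOX2, NANOG, KLF4, CD44, CD24, ITGA6, PROM1, CDH1, VIM, SNAI1, SNAI2, TWIST1, ZEB1, NOTCH4 and LEFTY1. MYC, ALDH1A1 and WNT3 were also fixed but are not among the 107 genes. Reference genes were not named as findings. Genes named outside this rule are said to be chosen after their values were seen.

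There were 14 gene lists: core pluripotency factors, the Cripto, Nodal and TGF-beta pathway, mesenchymal and EMT genes, epithelial and MET genes, breast cancer stem cell markers, the Notch, Wnt and Hedgehog pathways, germ layer and lineage genes, endothelial and blood cell markers, stromal fibroblast markers, NRF2 and sulforaphane response genes, cell cycle and proliferation genes, and reference genes. The 8 lists with at least 3 measured members were tested with camera, with a preset correlation of 0.01 and with an estimated correlation, and with fry, each adjusted over the 8 lists. Camera compares a list with the other genes, while fry tests whether a list moves, on balance, one way. The comparisons, the test, the rule for named genes and the lists were fixed before the data were examined.

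The settings varied in advance were a fit of the compared groups alone, a pseudocount of 10 in place of 1, mean signal of at least 20 or 50, and centring each sample on its median gene or its reference genes. Quantile normalization, an intensity trend, robust eBayes, array weights, a permutation test, a replicate block, the study's threshold and leaving out each sample belonged to the same set. Other settings were chosen after seeing the data. The first left out the 2 samples whose total signal was under 0.5 of the median, which are growth SFN replicate 1 and initiation SFN replicate 3. The others separated growth replicates 1 to 6 from growth replicates 7 to 12, because the step between neighbouring signal values was below 1 in 12 of 12 tumours of the lower-numbered set and in 2 of 12 of the other (Fisher's exact p = 6.73e-05). These sets hold equal numbers of SFN and saline tumours. The assay run of each sample is not given in the sources used here. The highest correlation between any pair of samples was 0.994, and 0 columns were identical. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.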

Results

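The experiment measured 107 human transcripts in 36 xenograft tumours of MDA-MB-231 D3H1 Luc breast cancer cells from mice given sulforaphane (SFN) or saline. There were 12 growth tumours with SFN, 12 growth tumours with saline, 6 initiation tumours with SFN and 6 initiation tumours with saline. The most abundant transcripts included mesenchymal ones. VIM (vimentin, an intermediate filament of mesenchymal cells) averaged a signal of 112300 over the 36 tumours, GAPDH 80332, EEF1A1 70625 and FN1 (fibronectin) 44208. CTNNB1 (beta-catenin) averaged 17757, the surface glycoprotein CD44 7316, LAMB1 (a laminin chain) 6910, PODXL 5596 and the integrin ITGA6 3667. FN1, CTNNB1, LAMB1 and PODXL are named for their abundance, after their values were seen. The pluripotency factors NANOG and POU5F1 (OCT4) averaged 280 and 232, and the epithelial cadherin CDH1 had group means from 6.56 to 11.03.

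The total signal over the 107 probes ranged from 302577 to 557588 in growth saline tumours (mean 441943 ± 76522, SD, n = 12). It ranged from 134503 to 525304 in growth SFN tumours (410230 ± 114010, SD, n = 12) and from 454977 to 616927 in initiation saline tumours (543354 ± 65867, SD, n = 6). Among initiation SFN tumours 5 lay between 583931 and 669499, and replicate 3 reached 71318, with 44 probes at the floor of 1. Growth SFN replicate 1, at 134503, was the other sample under 0.5 of the median total.

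**Figure D1:**
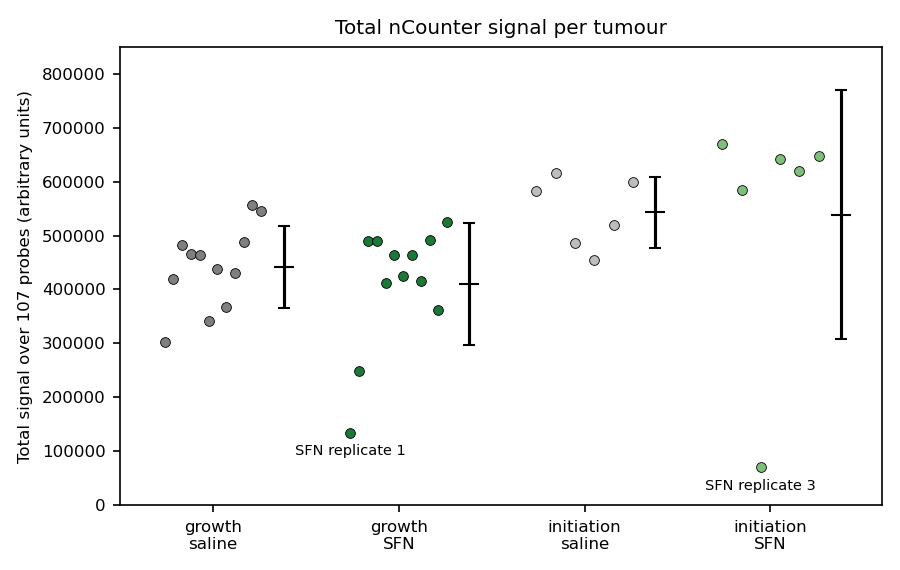
Total nCounter signal over the 107 probes (arbitrary units) for each of the 36 tumours, by group. Points are tumours, and the bar beside each group gives the mean with the SD. Growth SFN replicate 1 (134503) and initiation SFN replicate 3 (71318) sit far below the other tumours of their groups.

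The comparison of SFN with saline in growth tumours asks whether the treatment changed stem cell and EMT-MET genes in established tumours. In SFN tumours 4 genes fell and 0 rose, but 0 passed with median centring, reference gene centring or quantile normalization. AFP (alpha-fetoprotein, a fetal liver and yolk sac protein) had a mean signal of 25.7 ± 17.2 with SFN against 70.9 ± 39.6 with saline (SD, n = 12 each), and fell by 1.69 on the log2 scale (SE 0.42, adjusted p = 0.0287). FOXD3, a transcription factor of pluripotent and neural crest cells, had 40.5 ± 12.7 against 81.1 ± 26.8 and fell by 0.97 (SE 0.27, adjusted p = 0.0430). PROM1 (CD133, a surface marker of stem-like tumour cells) had 39.1 ± 20.7 against 85.3 ± 45.8 and fell by 1.11 (SE 0.32, adjusted p = 0.0430). SOX17, an endoderm transcription factor, had 37.2 ± 18.0 against 90.5 ± 50.1 and fell by 1.28 (SE 0.38, adjusted p = 0.0430). Each of the 4 lay below the saline mean in 12 of 12 SFN tumours. Here and in the counts that follow, that mean is of log2(signal + 1), not the signal mean printed beside it. Of the SFN tumours, 4 (AFP), 5 (FOXD3), 3 (PROM1) and 5 (SOX17) lay below every saline tumour.

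Among the 23 core pluripotency factors in the codeset, 1 fell (FOXD3) over all genes tested and 7 fell adjusted over the list alone; 22 of the 23 differences were below 0, with a median of -0.57, which was -0.13 with median centring and -0.09 with quantile normalization. NANOG, a core factor of embryonic stem cells, had 260 ± 109 against 495 ± 215 (log2 difference -0.91, SE 0.39, adjusted p = 0.114) and lay below the saline mean in 12 of 12 SFN tumours. SOX2 differed by -1.10 (SE 0.38) and DPPA4 by -1.36 (SE 0.43), each with an adjusted p of 0.0618 and below the saline mean in 12 of 12. POU5F1 had 227 ± 64.0 against 337 ± 147 (-0.49, SE 0.44, adjusted p = 0.635, 11 of 12 below the saline mean). The list did not pass fry (adjusted p = 0.152) or camera (adjusted p = 0.0923, or 0.641 with an estimated correlation). NANOG, POU5F1, TDGF1 and DPPA3 have 11, 6, 6 and 12 further loci named as their copies in the RefSeq annotation, so the locus behind their signal is uncertain.

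Of the 9 measured genes of the Cripto, Nodal and TGF-beta pathway, 0 passed in the main limma fit over all genes tested and 3 fell adjusted over the list alone. In that fit 8 of 9 were below 0, with a median of -0.77, which was -0.33 with median centring and -0.11 with quantile normalization. Among other planned settings, GDF3, LEFTY1 and LEFTY2 passed as lower with only the compared groups in the fit. With a pseudocount of 10, GDF3, LEFTY2, TDGF1P3 and TDGF1 did. Array weights called GDF3, LEFTY1, LEFTY2 and TDGF1P3 as lower, and the permutation test GDF3 and LEFTY1. The replicate block, the limits on mean signal, the intensity trend and robust eBayes called none of the 9. The rescalings of the samples called none of the 9. TDGF1 (Cripto-1, a co-receptor for Nodal) had 100.1 ± 42.8 against 183 ± 93.9 (-0.80, SE 0.37, adjusted p = 0.155, 11 of 12 below the saline mean). TDGF1P3, a Cripto-related gene copy, differed by -1.29 (SE 0.42, adjusted p = 0.0618, 10 of 12). The growth factor NODAL differed by -0.77 (SE 0.39, adjusted p = 0.214, 11 of 12). The Nodal antagonists LEFTY2 and LEFTY1 differed by -1.27 (SE 0.43, adjusted p = 0.0618) and -0.69 (SE 0.38, adjusted p = 0.275), below the saline mean in 12 of 12 SFN tumours for each. Of the 10 germ layer and lineage genes, 2 fell (AFP and SOX17), also adjusted over the list alone, and all 10 were below 0 (median -0.63, and -0.19 and -0.04 with these settings). The fry test gave an adjusted p of 0.152 for both lists. Camera gave 0.0923 for the pathway, and no list passed camera in this comparison.

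Mesenchymal and epithelial genes showed no passing change in growth tumours in the main fit. Of 15 mesenchymal and EMT genes and 4 epithelial and MET genes, 0 passed in it, over all genes or over the list alone. Among other settings, SNAI1, ZEB1 and FOXC2 passed as lower with array weights, and FOXC2 and GSC with a pseudocount of 10. FOXC2 also passed as lower within replicates 7 to 12. The rescalings of the samples called none of these lists' genes. FOXC2 and GSC are named here after their values were seen. VIM had 102677 ± 30386 against 108751 ± 17889 (-0.16, SE 0.28, adjusted p = 0.830, 4 of 12 below the saline mean). TWIST1 differed by -0.73 (SE 0.42, adjusted p = 0.293, 10 of 12), SNAI1 by -0.49 (SE 0.38, adjusted p = 0.490, 11 of 12), ZEB1 by -0.25 (SE 0.17, adjusted p = 0.422, 7 of 12) and SNAI2 by -0.14 (SE 0.48, adjusted p = 0.873, 5 of 12). CDH1 differed by -0.63 (SE 0.40, adjusted p = 0.374, 7 of 12). The EMT list had a median of -0.16, which turned to 0.29 with median centring and 0.02 with quantile normalization, and the epithelial list a median of -0.26, which turned to 0.18 and 0.16. Camera set both lists higher than the other genes despite these negative medians, and neither passed it. Their fry adjusted p was 0.597 and 0.494.

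Of the 8 breast cancer stem cell markers, PROM1 alone fell, over all genes and over the list alone. The median of the list was -0.35, which turned to 0.09 with median centring (fry adjusted p = 0.304). CD44, high on breast cancer stem cells, had 6670 ± 2386 against 7273 ± 1532 (-0.22, SE 0.41, adjusted p = 0.833, 6 of 12 below the saline mean). CD24, low on those cells, had 1020.1 ± 273 against 973 ± 215 (0.06, SE 0.20, adjusted p = 0.873, 5 of 12 above the saline mean). ITGA6 differed by -0.36 (SE 0.52, adjusted p = 0.819, 7 of 12 below). The 3 stromal fibroblast markers (ACTA2, COL1A1 and COL3A1) had a median of 0.05 with 0 passing, and the 4 reference genes a median of -0.10 with 0 passing, which turned to 0.34 with median centring, 0.01 with reference gene centring and 0.09 with quantile normalization. NOTCH4 differed by -0.37 (SE 0.48, adjusted p = 0.819), and with NUMB it forms the Notch list, whose median of -0.25 turned to 0.19 with median centring and 0.02 with quantile normalization. CTNNB1, the measured Wnt gene, differed by -0.23 and PECAM1, an endothelial gene, by -0.15; neither passed, and both turned with median centring, to 0.22 and 0.29. The measured transcripts are human and the host is the mouse. In every comparison, PECAM1 and the 3 stromal markers therefore need not report host endothelium or fibroblasts. No Hedgehog, NRF2 or cell cycle gene of the lists was measured.

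Over all 107 genes, 94 differences were below 0, with a median of -0.33, and 27 genes had an unadjusted p below 0.05, all lower with SFN (2 of 8 were higher with median centring, 0 of 20 with reference gene centring and 4 of 10 with quantile normalization). Relative to that median the pluripotency list lay at -0.25, the Cripto and Nodal list at -0.44, the lineage list at -0.30 and the EMT list at 0.17. Leaving out single tumours gave between 0 and 23 genes. The 4 calls were lost under each rescaling of the samples: the median gene then stood at 0.11 with median centring, -0.22 with reference gene centring and -0.01 with quantile normalization, and AFP at -1.25, -1.59 and -1.02. In the same order FOXD3 stood at -0.53, -0.86 and -0.33, PROM1 at -0.67, -1.001 and -0.50, and SOX17 at -0.84, -1.17 and -0.69. In limma under these rescalings, their adjusted p and that of AFP ran from 0.0559 (FOXD3, reference gene centring) to 0.547 (PROM1, quantile normalization). Median centring and quantile normalization take out a shift shared by most of the 107 genes, whatever its cause. The loss there therefore cannot separate a scaling artefact from an effect of SFN. With reference gene centring the differences shrank less. The SE then rose for AFP (0.42 to 0.51), PROM1 (0.32 to 0.41) and SOX17 (0.38 to 0.40) and fell for FOXD3 (0.27 to 0.23). The calls were also lost within growth replicates 1 to 6 (AFP -2.002, SE 0.60, adjusted p = 0.2998; FOXD3 -0.97; PROM1 -1.14; SOX17 -1.41), while within replicates 7 to 12 AFP passed (-1.38, SE 0.28, adjusted p = 0.00688) and FOXD3 (-0.97), PROM1 (-1.07) and SOX17 (-1.15) did not. Without the 2 samples of low total signal 11 genes fell, the 4 and ZFP42, NANOG, LEFTY1, DPPA3, T, DPPA4 and TDGF1P3, and fry gave an adjusted p of 0.0110 for the pluripotency, 0.0185 for the Cripto and Nodal, 0.0110 for the lineage and 0.0317 for the stem cell marker list. Camera with an estimated correlation then gave adjusted p of 0.548, 0.590, 0.548 and 0.911 for these lists.

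**Figure D2:**
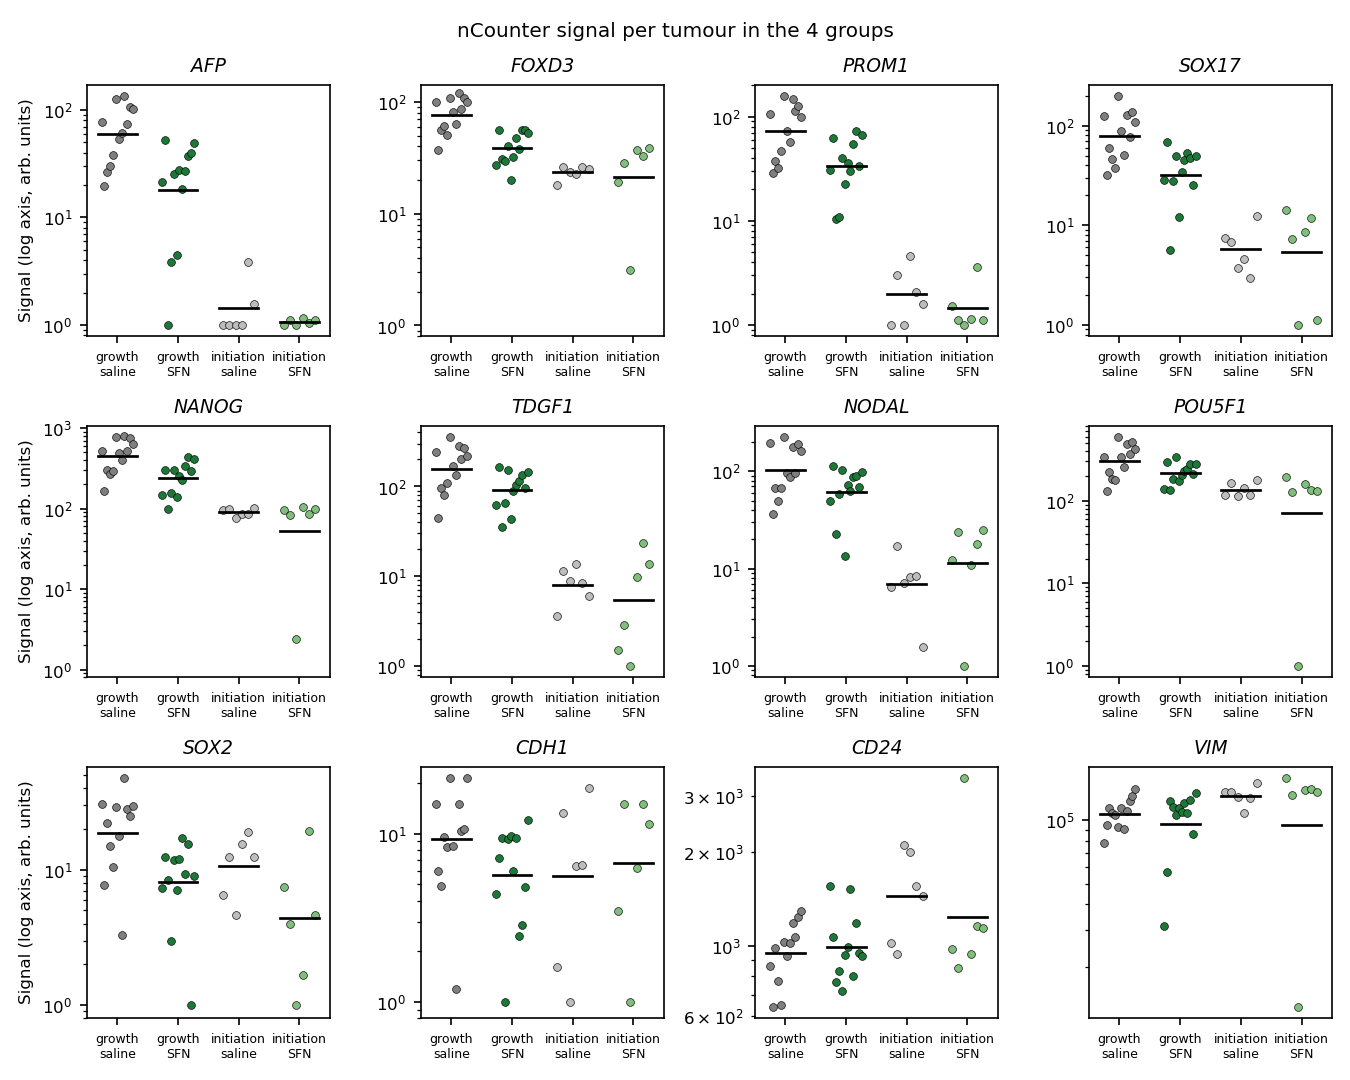
Signal per tumour (log axis, arbitrary units) of 12 genes in the 4 groups, with points for tumours and a horizontal line at the mean of log2(signal + 1) turned back to signal. AFP, FOXD3, PROM1 and SOX17 lay below the growth saline mean in 12 of 12 growth SFN tumours. AFP, PROM1, TDGF1 and NODAL lay in 6 of 6 initiation saline tumours below all 12 growth saline tumours. The mean differences of these genes kept their sign under each scaling, but the calls of AFP, FOXD3, PROM1 and SOX17 with SFN in growth tumours were lost under each rescaling.

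The comparison of SFN with saline in initiation tumours asks about the same genes early after cell injection. No gene passed in limma, and 4 genes had an unadjusted p below 0.05, all lower with SFN (8 of 11 were higher with median centring, 1 of 10 with reference gene centring and 5 of 8 with quantile normalization). COL1A1, a fibrillar collagen of fibroblasts, differed by -1.09 (SE 0.49) and lay below the saline mean in 6 of 6 tumours. The nuclear receptor NR6A1 differed by -1.32 (SE 0.64), SOX2 by -1.10 (SE 0.54) and REXO1 by -1.32 (SE 0.65), each below the saline mean in 5 of 6. The adjusted p was 0.504 for all 4. Without the samples of low total signal, which here removes replicate 3, REXO1 stood at -0.20, COL1A1 at -0.35, NR6A1 at -0.90 and SOX2 at -0.81, and of the genes that follow NANOG at 0.04, TDGF1 at -0.13 and CD44 at 0.11. NANOG had 78.2 ± 38.0 with SFN against 90.8 ± 10.01 with saline (SD, n = 6 each), a difference of -0.76 with a 95% interval from -1.86 to 0.35 in limma (3 of 6 below the saline mean), which turned to 0.07 with quantile normalization. TDGF1 had 8.67 ± 8.75 against 8.63 ± 3.64 (-0.47, interval from -1.52 to 0.58), which turned to 0.28 with median centring. NODAL had 15.2 ± 9.03 against 8.13 ± 5.04 (0.67, interval from -0.45 to 1.79) and lay above the saline mean in 5 of 6. CD44 differed by -0.85 (interval from -2.03 to 0.34) although 5 of 6 tumours lay above the saline mean.

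In initiation tumours 0 members of any list passed in limma, over all genes or over the list alone, and no list passed fry or camera. The medians were -0.51 for pluripotency factors, -0.19 for the Cripto and Nodal pathway, -0.39 for lineage genes, -0.46 for EMT genes, -0.19 for epithelial genes, -0.38 for stem cell markers and -0.75 for stromal markers. The 4 reference genes had -0.38, the Notch genes -0.55, CTNNB1 -0.24 and PECAM1 -1.09, and with median centring PECAM1 alone stayed below 0, at -0.34, with the stromal median at 0.003 and the pluripotency median at 0.24. The median over all 107 genes was -0.49 and became 0.25 with median centring, -0.10 with reference gene centring and 0.04 with quantile normalization. Without the samples of low total signal the all-gene median was 0.11, and the pluripotency, Cripto and Nodal, lineage, EMT, epithelial and stem cell marker medians turned to 0.11, 0.15, 0.08, 0.04, 0.26 and 0.03, while the stromal median stayed below 0 at -0.23 and PECAM1 at -0.03. That setting gave 0 passing genes in limma, 9 at an unadjusted p below 0.05, of which 8 were higher with SFN, NODAL at 1.20 and LEFTY1 at 0.72 (adjusted p = 0.435 for both). The smallest exact p that 6 against 6 tumours allow is 0.00216.

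**Figure D3:**
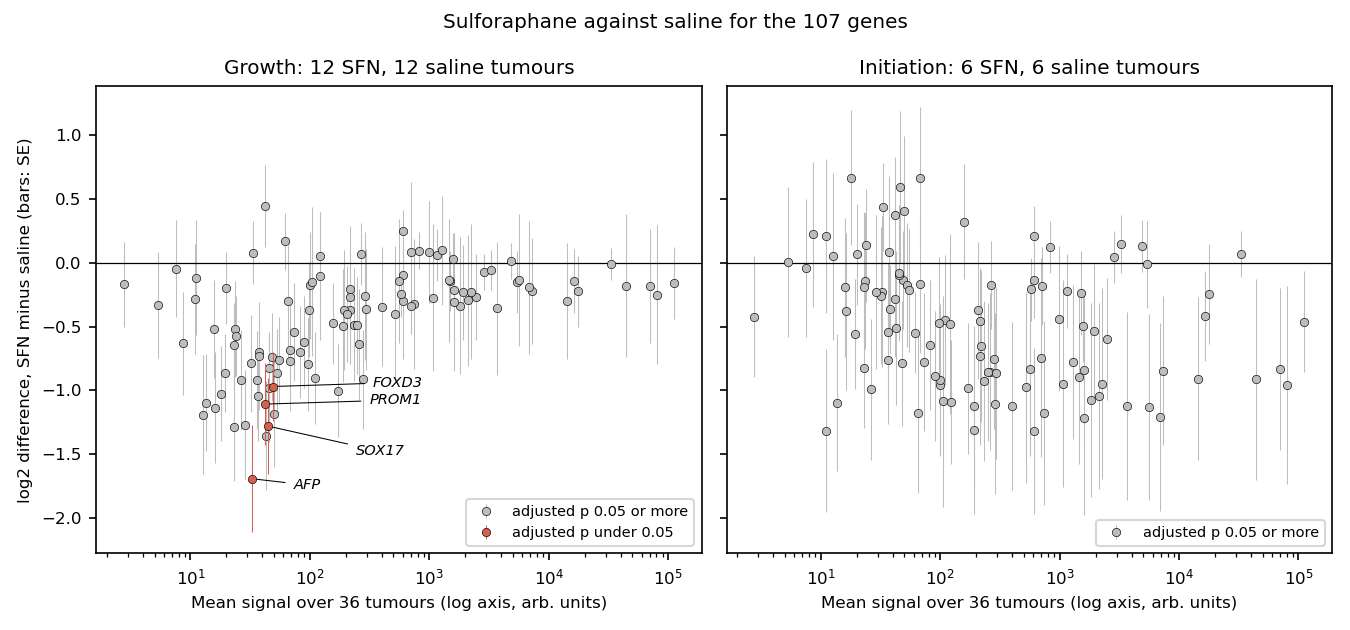
Log2 difference of SFN minus saline for each of the 107 genes (bars, SE) against its mean signal over the 36 tumours (log axis, arbitrary units), in growth and in initiation tumours. The 4 genes with an adjusted p below 0.05 (AFP, FOXD3, PROM1 and SOX17) have a mean signal below 50, and their calls were lost under median centring, reference gene centring and quantile normalization; in initiation tumours 0 genes passed.

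The difference between the effects of SFN in initiation and growth tumours was tested directly. No gene passed in limma, and 4 genes had an unadjusted p below 0.05, each with a less negative or positive difference in initiation tumours. These were UTF1, a chromatin factor of embryonic stem cells, at 1.69 (SE 0.65), the gonadal hormone receptor LHCGR at 1.59 (SE 0.72), the organiser gene GSC at 1.58 (SE 0.72) and NODAL at 1.44 (SE 0.68), all with an adjusted p of 0.850. For the genes that fell in growth tumours the difference was 1.47 for AFP, 1.20 for SOX17, 0.84 for FOXD3 and 0.83 for PROM1, also with adjusted p of 0.850, so the effects were not shown to differ between the stages. The Cripto and Nodal list had a median of 0.73 and the stromal list of -0.83; each passed camera (adjusted p = 0.0468) but had an adjusted p of 0.666 with an estimated correlation. Without the 2 samples of low total signal 3 genes passed, LEFTY1 at 1.31 (SE 0.29, adjusted p = 0.0101), FOXD3 at 1.28 (SE 0.33, adjusted p = 0.0235) and the pluripotency marker ZFP42 (REX1) at 1.20 (SE 0.34, adjusted p = 0.0470). ZFP42 is named after its values were seen.

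The series design names SFN against saline over all samples, which corresponds to the mean of the effects in both stages. No gene passed in limma, while 24 had an unadjusted p below 0.05, all lower with SFN, whereas with median centring 13 did, all higher, with reference gene centring 15, all lower, and with quantile normalization 11, 7 of them higher. SOX2 differed by -1.10 (SE 0.33), the germline and pluripotency gene DPPA3 by -0.99 (SE 0.32), AFP by -0.96 (SE 0.36), WT1 by -0.90 (SE 0.31), NANOG by -0.84 (SE 0.33) and PROM1 by -0.69 (SE 0.28), each with an adjusted p of 0.155. SOX2 lay below the saline mean of its stage in 12 of 12 growth and 5 of 6 initiation SFN tumours. TDGF1 differed by -0.63 (SE 0.32, adjusted p = 0.204) and POU5F1 by -0.71 (SE 0.38, adjusted p = 0.240). Of the pluripotency list 0 passed over all genes and 2 fell adjusted over the list alone (median -0.59, and 0.01 with median centring). The fry test gave an adjusted p of 0.0985 for the pluripotency, stem cell marker and lineage lists, and no list passed camera. The median over all genes was -0.52 and -0.03 without the 2 samples of low total signal, and 0.07, -0.27 and -0.02 with median centring, reference gene centring and quantile normalization.

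Saline tumours of the initiation and growth stages differed widely, with 39 genes passing, 36 lower and 3 higher at initiation. PROM1 had 2.22 ± 1.40 at initiation (SD, n = 6) against 85.3 ± 45.8 at growth (n = 12) and was lower by a log2 difference of -4.63 (SE 0.39, adjusted p = 6.63e-12). AFP had 1.58 ± 1.15 against 70.9 ± 39.6 (-4.65, SE 0.51, adjusted p = 2.33e-09). TDGF1 had 8.63 ± 3.64 against 183 ± 93.9 (-4.14, SE 0.45, adjusted p = 2.33e-09) and NODAL 8.13 ± 5.04 against 121 ± 65.2 (-3.74, SE 0.48, adjusted p = 3.33e-08). NANOG had 90.8 ± 10.01 against 495 ± 215 (-2.30, SE 0.47, adjusted p = 0.0001). All 6 initiation tumours lay below all 12 growth tumours for these 5 genes, and the differences stayed negative and past the threshold under each scaling. Other differences were those of the organiser gene GSC (-4.24), TDGF1P3 (-4.05), WT1 (-3.91), LEFTY2 (-3.80), MIXL1 (-3.59), SOX17 (-3.56), LHCGR (-3.56), the receptor KIT (-3.55), UTF1 (-3.34), TWIST1 (-3.24) and the Nodal antagonist CER1 (-3.15), with adjusted p from 2.33e-09 to 1.64e-06. For these 11, all 6 initiation tumours lay below all 12 growth tumours except for KIT, with 5 of 6.

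Of the 23 pluripotency factors 12 fell and 1 rose, over all genes and over the list alone (median -1.52, and 0.01 with quantile normalization, where 7 fell and 5 rose; fry adjusted p = 0.0170). Of the 9 Cripto and Nodal genes 5 fell over all genes, and 5 fell and 1 rose adjusted over the list alone (median -2.75, and -0.54 with quantile normalization, where 4 fell and 1 rose; fry adjusted p = 4.27e-05). Of the 10 lineage genes 7 fell, over all genes and over the list alone (median -1.83, and 0.10 with quantile normalization, where 4 fell and 2 rose; fry adjusted p = 0.00152). Of 15 EMT genes 3 fell, with a median of 0.31, which was 0 with quantile normalization, and a mean of -0.39 (fry adjusted p = 0.715). PROM1 and KIT were the stem cell markers that fell, of 8 measured (median 0.16, and -0.14 with reference gene centring, mean -0.80, fry adjusted p = 0.191). No epithelial, stromal, Notch or Wnt gene passed in limma, whereas with median centring 3 of 4 epithelial, 3 of 3 stromal, 2 of 2 Notch and the 1 Wnt gene passed as higher at initiation, as did 8 EMT genes. Without the samples of low total signal 28 genes passed as higher, among them 5 EMT genes, 2 stromal genes, 2 stem cell markers, and 1 each of the epithelial, Notch, Wnt and endothelial lists. The samples left out are SFN tumours, so the differences were unchanged and only the estimate of the spread moved. The 3 stromal markers had a median of 0.83 (fry adjusted p = 0.0612), the epithelial genes 0.15, the Notch genes 0.16, CTNNB1 0.56, PECAM1 1.26 and the reference genes 0.29, and with reference gene centring the epithelial, Notch and reference medians turned to -0.15, -0.14 and -0.01. No list passed camera, with the preset or with an estimated correlation.

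The 3 higher genes were FGF2, a growth factor for stem cells and fibroblasts, at 0.74 (SE 0.28, adjusted p = 0.0303, 6 of 6 above all 12 growth tumours), NR6A1 at 1.40 (SE 0.55, adjusted p = 0.0447, 6 of 6 above the growth mean), and a reference gene. The other probe for NR6A1, NR6A1-2, went the other way, with 31.2 ± 7.84 at initiation against 53.9 ± 25.1 at growth (-0.66, SE 0.30, adjusted p = 0.0854), and turned to 1.04 with quantile normalization; it is named after its values were seen. FGF2 and NR6A1 no longer passed with reference gene centring (0.44 and 1.10). CD24 differed by 0.60 (SE 0.25, adjusted p = 0.0543), POU5F1 by -1.16 (SE 0.54, adjusted p = 0.0952), VIM by 0.28 (SE 0.34, adjusted p = 0.532) and CD44 by 0.24 (SE 0.51, adjusted p = 0.749); the last pair turned to -0.02 and -0.07 with reference gene centring. SOX2 and CDH1 differed by -0.75 and -0.64 and turned to 1.61 and 1.77 with quantile normalization. The median of all genes was 0.03, and 0.64, -0.27 and 0.01 with median centring, reference gene centring and quantile normalization. TDGF1P3 was at the floor of 1 in 5 of the 6 initiation tumours, AFP and UTF1 in 4, and PROM1, WT1, LEFTY2, KIT and CER1 in 2. In initiation saline replicate 6 the lowest signal was 1.58, and AFP, PROM1, NODAL, LEFTY2, KIT and CER1 stood at that value. The floor thus limits the size of the differences of these genes, and the stage cannot be told apart from an assay batch. Against growth replicates 1 to 6 alone 30 genes passed, and against replicates 7 to 12 alone 38.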

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

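The tests of low RNA input and of host tissue were both chosen after the values of replicate 3 were seen. In each group of 6 initiation tumours, 46 measures (the named genes and the total) were searched for a value whose gap to its nearest neighbour was large for the range of the group, which happens by chance in about 1 of 20 groups.

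Initiation SFN replicate 3 held 24 of the 31 values found. Its total signal was 71318 against 583931 to 669499 in the other 5 tumours. VIM was 12992 against 131981 to 158728, CD44 168 against 8555 to 9598, ITGA6 31.7 against 4802 to 5709, SNAI2 16.7 against 1980 to 2547, and KLF4 165 against 735 to 883. ZEB1 was 254 against 657 to 774, REXO1 6.15 against 679 to 903, FGF2 26.4 against 55.5 to 75.1, COL1A1 5.40 against 111 to 163, SNAI1 4.64 against 191 to 271, and NOTCH4 1.64 against 340 to 411. NANOG was 2.39 against 83.9 to 105, and FOXD3 3.14 against 19.3 to 38.3. POU5F1, NODAL, LEFTY1, DPPA3, DNMT3B, CRABP2, GATA3, MSI1 and NTN1 were each at the floor of 1, where the other 5 tumours had lowest values from 10.8 (NODAL) to 190 (NTN1). CD24 went the other way, at 3433 against 850 to 1159.

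For this sample, low RNA input or a failed lane would put every well-expressed probe below the other tumours in unscaled values. Of 57 probes with a mean of at least 100 in the other 5 tumours, 5 (BMP2, CD24, SMARCA2, TCF4 and ZEB2) reached at least the lowest of them. The scaling is unknown and could lift probes of a weak sample, so this count alone decides nothing. The log2 deviations ran from -8.65 (REST, 3.14 against a mean of 1661) to 1.77 (CD24), with a median of -6.06. A single scaling factor would shift all probes alike and would not give this spread. The spread argues against low input as the whole cause. A candidate explanation is host tissue in place of most of the human tumour: across probes, the deviations followed those of the other low sample, growth SFN replicate 1 (Spearman rho 0.828, permutation p = 1e-05, the smallest that the permutations can give; probes are not independent replicates). In that growth sample the deviations ran from -2.74 to 0.94, with a median of -1.66. A small early tumour, a missed dissection, another sample in place of this tumour and an effect of SFN on tumour take stay open, and no mouse-specific probe was measured that would tell them apart.

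The other 7 values were single tumours near the floor or within a narrow range. In initiation saline tumours AFP was 3.87 in replicate 5 against 1 to 1.58, and TDGF1P3 was 4.39 in replicate 6 against 1 in the other 5. DNMT3B was 155 in replicate 6 against 72.7 to 95.4, DPPA4 was 1.16 in replicate 2 against 9.14 to 24.3, and GDF3 was 1.62 in replicate 1 against 9.59 to 21.7. In initiation SFN tumours LHCGR was 1.52 in replicate 1 against 9.12 to 14.4, and PROM1 was 3.61 in replicate 5 against 1 to 1.52.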

How the results depend on the processing

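The settings without the samples of low total signal and those on growth replicates 1 to 6 and 7 to 12 were chosen after seeing the data; the others were planned. In growth tumours, where 4 genes fell, 18 passed with only the compared groups in the fit, 27 with a pseudocount of 10, 25 with array weights, 11 without the samples of low total signal, 8 with the replicate sets as a block and 27 at the study's threshold, with all 4 genes in each of the first 5 sets. The permutation test gave 7 (without PROM1) and the replicate block 2 (AFP and PROM1). The count was 0 with a mean signal of at least 50, which removes all 4 genes, 0 with median centring, reference gene centring or quantile normalization, and 0 with only growth replicates 1 to 6, which leaves fewer samples. Mean signal of at least 20, intensity trend and robust eBayes kept the same 4 genes; only replicates 7 to 12 gave 3 with AFP shared. Leaving out single tumours gave 0 to 23 genes, all lower: SFN replicates 1 to 12 gave 1, 13, 0, 0, 4, 0, 1, 1, 4, 7, 2 and 14, and saline replicates 1 to 12 gave 0, 23, 4, 8, 14, 0, 1, 6, 0, 0, 0 and 0. In initiation tumours (0 genes) 4 passed at the study's threshold, and 0 under each other setting and each tumour left out. For the stage difference (0 genes) 9 passed with array weights, 3 without the samples of low total signal and 4 at the study's threshold; leaving out single tumours gave 0 to 3, with 3 without initiation SFN replicate 3. For the mean effect (0 genes) 22 passed at the study's threshold; single tumours gave 0 to 1, with 1 without growth saline replicate 8 or initiation SFN replicate 5.

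For initiation against growth in saline (39 genes, 3 higher and 36 lower), 66 passed with only the compared groups (24 higher), 13 with a mean signal of at least 50, 85 with median centring (51 higher and 34 lower), 76 with array weights (32 higher), 68 with the permutation test (26 higher) and 72 without the samples of low total signal (28 higher). Quantile normalization gave 46 (21 higher and 25 lower), the other settings 30 to 46, and single tumours 36 to 41. The 2 samples of low total signal are SFN tumours and lie outside this contrast. Leaving them out, or fitting only the compared groups, left the differences unchanged (median 0.03, 53 lower and 54 higher). The added calls of those settings thus came from the estimate of the spread, which all 36 tumours share in the main fit. The cause of the other shifts was not tested beyond the smaller sets named. Values that reversed were CDH1 at 1.77 and SOX2 at 1.61 with quantile normalization and NOTCH4 at 0.51 with median centring, each in initiation against growth in saline, and NOTCH4 at 0.56 with array weights in the stage difference. Of 1026 values of named genes in the growth comparison, 885 kept their side of the threshold without a reversal of a called direction, 19 of all the values changed sign without being called in either setting, 72 no longer passed, 69 newly passed and 0 reversed. The replicate block was not run for the saline comparison, whose blocks do not cross the stages, and replicate numbers did not pair samples, with 1 of 12 growth and 1 of 6 initiation tumours closest to their own number. Signal over background limits AFP, PROM1, TDGF1P3 and UTF1 in initiation tumours, which sit near the floor of 1.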

Other observations

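The tests of a shared signal component and of genomic copies used genes and limits chosen after their values were seen, and the test of abundant transcripts was chosen after its result was seen. Further genes were lower at initiation. Signal of the gonadal receptor LHCGR was 94.1 ± 45.7 in growth saline (SD, n = 12), 46.0 ± 24.3 in growth SFN (n = 12) and 8.50 ± 7.18 in initiation saline tumours (n = 6). CALB1, a calcium-binding protein of neurons and kidney, had 197 ± 92.2, 110.1 ± 58.4 and 24.0 ± 6.56, and CGB, the placental chorionic gonadotropin subunit, 438 ± 218, 271 ± 108 and 77.1 ± 23.3. At initiation against growth in saline, all 3 passed in limma, lower by log2 differences of -3.56 (SE 0.51, adjusted p = 2.56e-07), -2.85 (SE 0.44, adjusted p = 1.06e-06) and -2.34 (SE 0.53, adjusted p = 0.000400). The mesoderm factor T (-2.27, SE 0.42), the telomerase gene TERT (-1.54, SE 0.44), the intestinal factor CDX2 (-2.03, SE 0.47), the RNA-binding protein LIN28A (-1.88, SE 0.44) and the secreted Wnt modulator SFRP2 (-1.51, SE 0.49) were also lower. In growth tumours LHCGR, CALB1 and CGB did not pass between SFN and saline (-1.18, -0.91 and -0.64, adjusted p = 0.0618, 0.0925 and 0.416). Except for LHCGR in the saline comparison, these genes were chosen after their values were seen, and no list or enrichment test was run on them as a set.

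In growth tumours a signal component that the genes that fell with SFN share with genes of unrelated tissues cannot be told apart from an effect of SFN. With the mean log2 signal of LHCGR, CALB1 and CGB as a covariate, the median difference of the 4 called genes moved from -1.19 (SE 0.35) to -0.47 (SE 0.25), and 0 of the 4 passed, because the difference shrank while its SE did not grow (without the samples of low total signal -0.51, and FOXD3 passed, adjusted p = 0.0498), but the covariate genes were chosen because they moved with AFP, and 2 of the 3 had an unadjusted p below 0.05 here (LHCGR 0.00751, CALB1 0.0164), so this decides nothing. Genomic DNA is a candidate source. Across 62 genes with a mean signal below 300, the slope of a gene's signal on AFP, LHCGR and CALB1 in growth SFN tumours was higher, on balance, with more annotated copies (Spearman rho 0.508 across genes, which are not independent replicates, permutation p = 1e-05, the smallest that the permutations can give). The median slope was 1.10 for the 10 genes with copies and 0.217 for the rest, and growth saline tumours, seen first, gave a rho of 0.541. A slope in signal units can also rise with a gene's level, which was not held constant, so copies and level cannot be told apart. Some copy-bearing genes had a high mean signal (NANOG 280, POU5F1 232) and others a lower one (TDGF1 97.3, DPPA4 42.8). AFP, a called gene, was among the 3 slope genes, and FOXD3, PROM1 and SOX17 have 0 annotated extra copies. A lower share of human cells as the whole cause is argued against by 8 abundant transcripts, whose median differed by -0.21 (SE 0.23) where the called genes had -1.19. An effect of SFN on these genes stays open. Of 100 splits of the growth tumours, 1, the real one, gave as many as 4 genes (highest other 0). With 100 splits drawn, a chance split is less likely but is not excluded. The count of 4 itself moved between 0 and 23 when single tumours were left out.

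The slopes per copy-bearing gene, in signal per unit of the mean of the 3 genes, were 3.09 in growth SFN and 3.62 in growth saline tumours for NANOG with 11 copies, 2.13 and 2.44 for DPPA3 with 12, 1.66 and 2.45 for POU5F1 with 6, and 1.28 and 1.60 for TDGF1 with 6. They were 0.934 and 1.07 for LIN28A with 3, 0.509 and 0.945 for TERF1 with 7, and 0.461 and 0.466 for DPPA4 with 3. Of the genes with 1 copy, SNAI1 had 1.34 and 1.35, ZEB2 0.621 and 0.892, and OCLN 0.290 and 0.657. Copies did not order the genes strictly: SNAI1 exceeded TDGF1 in growth SFN tumours, and BMP2 (1.13 and 1.33), NODAL (0.898 and 1.06), TERT (0.876 and 1.29) and MSI1 (0.824 and 1.33), with 0 copies, exceeded TERF1 and DPPA4 in both groups. Within the 46 genes that followed the 3 genes with r above 0.5 in growth saline tumours, rho in growth SFN tumours was 0.521 (permutation p = 0.00023), again without holding the signal level constant.

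For the low signal of pluripotency and lineage genes in initiation saline tumours, the covariate decides nothing about a shared component: LHCGR, CALB1 and CGB fell in the same comparison and were chosen after their values were seen, so a smaller difference follows from their choice. With it the median difference of 33 genes that fell moved from -2.80 (SE 0.46) to -0.57 (SE 0.49), and 4 (AFP, PROM1, TDGF1 and WT1) still passed; without the samples of low total signal it moved to -0.66, and PROM1 and TDGF1 alone of the 33 still passed. A change of these genes with tumour age, a different assay batch and a different carry-over of DNA stay open and cannot be told apart. Of 100 splits of the saline tumours, 1, the real one, gave as many as 39 genes (highest other 26). With 100 splits drawn, a chance split is less likely but is not excluded. A split that keeps most initiation tumours together would call genes through the stage difference itself. Whether the split with 26 genes did so was not checked.

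For the comparisons with 0 genes, the splits say nothing about chance, since any split gives at least 0. All 100 splits therefore counted in initiation tumours (highest other 3), for the stage difference (highest other 13) and for the mean effect (highest other 1). What made a split of the stage difference call 13 genes where the real one calls 0 was not tested. Over the 107 genes, 84 had the same sign of the SFN difference in both stages, and 39 had it without the samples of low total signal. These counts follow the share of genes below 0, which was 94 in growth and 87 in initiation tumours. Without the samples of low total signal it was 88 and 34. The Pearson r of the differences across genes was -0.12, and 0.14 without those samples. The counts alone therefore show no agreement between the stages, nor a loss of it.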
